A study of Mus musculus with 6 samples.

How the data were processed

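Kidney RNA of 6 libraries was analysed, 3 of dissociated cells and 3 of nuclei, with 1 library for each preparation in control, 17 min and 27 min kidneys. Per the labels, libraries were made with a 10x Chromium 3' kit of version 3 and sequenced 2 times. The authors made the deposited matrices of raw UMI counts per gene and barcode with Cell Ranger 3.0.2 and STAR on mm10, keeping the barcodes that Cell Ranger called as cells. The labels do not state whether intronic reads were counted, for either preparation. Library totals ran from 47919366 to 101215052 UMIs in cells and from 9811956 to 15446969 in nuclei. Of 31053 gene identifiers, 30934 matched a GENCODE M21 model on GRCm38, which gave positions and lengths.

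Gene lists, cell type markers, the rule for named genes, the tests and most alternatives were chosen before the data were examined. Barcodes were kept with at least 200 genes and at most 50% mitochondrially encoded UMIs. Doublets were called with the scrublet of scanpy 1.11.5 as the highest scores, 0.4% of barcodes per 1000 barcodes of the library (0.8% expected), a rule set after the data were seen, since the automatic threshold called 3, 0 and 0 barcodes in control, 17 min and 27 min nuclei. This removed 626, 1595 and 284 barcodes in control, 17 min and 27 min cells and 231, 230 and 128 in nuclei. Cells and nuclei were clustered apart, on log-normalised counts of 2000 variable genes, 30 principal components, 20 neighbours and Leiden (leidenalg 0.10.2) at a resolution of 1, with a random seed of 0. A marker counted for a cluster at a log2 fold of at least 1 over other barcodes (pseudocount 10 CPM) and detection in at least 10% of its barcodes. A cluster took the class with the largest mean log2 fold over its markers, those not counted entering as 0, given at least 3 counted markers. It stayed unnamed if its top 10 genes held more markers of another class, or if they held none of its own and its median UMI count was under 1/3 of that of its libraries. Rebuilt names can differ from those of the study. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

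Counts were summed per library, over all deposited barcodes and over each class with at least 50 barcodes in all 6 libraries (proximal tubule, distal tubule, endothelial, immune and intercalated). Barcodes were never replicates. Preparations were compared with edgeR 4.0.16 (R 4.3.3) in a quasi-likelihood fit with preparation and injury state as terms, which leaves 2 residual degrees of freedom, after filterByExpr and TMM scaling. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. The 22 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation beside it, and with fry, which tests whether a list's genes move one way and not how they compare with other genes. Lists were mitochondrially encoded, ribosomal protein, respiratory chain, immediate early, heat shock, nuclear-retained, long, tubular injury, proximal tubule transport, fatty acid oxidation, glycolysis, NRF2, p53, cell cycle, chemokine, interferon, class II, matrix, hypoxia, cholesterol, immune marker and red cell genes. Of 14 nuclear-retained RNAs 10 were in the files, and of 26 matrix genes 25. The fit was tested on simulated data.

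Injury states were not tested, since each preparation had 1 library per state and nothing says that cells and nuclei of a state came from different animals. Folds are ratios of CPM with exact intervals from Poisson counts, and log2 folds add 1 CPM. Genes entered with at least 20 UMIs in the higher library of both preparations. List medians carry order-statistic 95% intervals over members, which do not cover variation between animals, and were ranked among 10000 random lists matched on expression in windows of 100 genes. Class shares carry exact binomial intervals and an exact paired sign-flip test of cells against nuclei. A share of 0 is given with the limit that 3 counts allow. Intervals of folds and shares and the limits cover counting error only, while those of list medians reflect spread over member genes.

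Named genes for the preparations were, among proximal tubule-like genes called with 1 direction in all 3 injury states and at least 50 CPM in the higher preparation, the 10 largest and 10 smallest folds without predicted gene models. To these came up to 4 tested members of smallest adjusted p per list, with no condition on call, direction or CPM. For the injury they were the 10 largest and 10 smallest folds at 27 min, ranked by the smaller absolute fold of the 2 preparations among genes with 1 direction in both, and up to 4 per list.

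Alternatives were no TMM, DESeq2 1.42.0, no filter on low counts, no injury term, mitochondrially encoded genes left out, sums thinned to the smallest library, each library or injury state left out, any fold change, TMM within each preparation, barcodes weighted equally or thinned to 500 UMIs, a pseudocount of 10 CPM, at least 100 UMIs, proximal and injured tubule-like barcodes together, at most 20% or any share of mitochondrial UMIs, called doublets kept, resolutions of 2 and 0.5, barcodes assigned one by one, and clusters made without mitochondrial, ribosomal and immediate early genes. Chosen after seeing the data were doublets at the automatic threshold, clusters made without tubular injury genes, sums over barcodes that pass the filters, and proximal, injured and unnamed nuclei clusters together.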

Results

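Left kidneys of male mice of the inbred strain C57BL/6JRj, 12 weeks old, were profiled either as dissociated single cells or as isolated nuclei, from control kidneys and from kidneys of 2 injury states named 17 min and 27 min. The series title names ischemia-reperfusion injury, in which blood flow to the kidney is stopped and then restored. The labels give neither the interval between injury and sampling nor whether cells and nuclei of a state came from the same animal. Each of the 6 combinations of preparation and injury state was measured in 1 droplet library (10x Chromium 3' chemistry, version 3), so 3 libraries per preparation and 2 per injury state. The values are raw counts of unique molecular identifiers (UMIs) per gene and barcode. Genes are named by symbol, and positions are on GRCm38 (mm10).

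The cell libraries held 13934, 20749 and 8626 barcodes in control, 17 min and 27 min, with 67603547, 101215052 and 47919366 UMIs. The nuclei libraries held 7905, 7674 and 5676 barcodes, with 15446969, 15068092 and 9811956 UMIs. Median UMIs per barcode ran from 2893 to 3531.5 in cells and from 1257 to 1556 in nuclei. Mitochondrially encoded transcripts took 48.2%, 27.1% and 17.7% of UMIs in control, 17 min and 27 min cells, and 27.0%, 19.8% and 11.6% in nuclei. Filters on genes, mitochondrial share and doublets left 6771, 14501 and 7206 cells and 6231, 6783 and 5360 nuclei. Clusters of these barcodes were named from kidney marker genes fixed beforehand, and each class is called like the type whose markers it carries.

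The first question was which cell classes each preparation recovered. Immune-like barcodes took a higher share of cells than of nuclei in all 3 pairs. Their share was 16.3% (exact binomial 95% interval 15.5 to 17.2), 48.9% and 62.3% in control, 17 min and 27 min cells, against 1.43% (1.15 to 1.75), 4.95% and 7.16% in nuclei. Cells exceeded nuclei by 38.0 ± 20.8 percentage points (SD, n = 3 pairs of libraries). Nuclei held more proximal tubule-like, distal tubule-like and stromal-like barcodes in all 3 pairs, with differences of −12.8 ± 8.78, −11.9 ± 1.12 and −4.60 ± 2.13 points. Shares are parts of a whole, so a higher immune-like share in cells leaves less for every other class there. Proximal and immune-like counts were 2048 and 1107, 3463 and 7085, and 1072 and 4490 in control, 17 min and 27 min cells. In nuclei they were 3313 and 89, 2123 and 336, and 1228 and 384. Outside the immune class, the proximal part was then lower in cells in control and higher at 17 min and 27 min. At 17 min and 27 min, however, 763 and 842 nuclei were injured tubule-like, against 524 and 487 cells. A further 782 and 1164 nuclei lay in an unnamed cluster that counted the injured tubule markers Havcr1 and Dcdc2a. Counting both groups with the proximal class would make this part higher in nuclei at 17 min and 27 min.

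Thin limb-like and urothelial-like clusters appeared in nuclei, at 2.07% to 3.90% and 0.970% to 1.17%. No cluster of cells took either name, which leaves 0 of 6771, 14501 and 7206 barcodes (by counting error alone, up to 0.0443%, 0.0207% and 0.0416%). Barcodes assigned one by one gave mean shares of 1.11% and 0.397% in cells, so that small groups of these cells within other clusters are not excluded. No nuclei cluster took the thin limb name at a resolution of 0.5 or in clusters made without tubular injury genes, an alternative chosen after seeing the data, and the mean share in nuclei went from 3.25% to 1.49% in clusters made without mitochondrial, ribosomal and immediate early genes. The mean urothelial-like share of nuclei, 1.07%, was 0.443% with at most 20% mitochondrial UMIs and 2.24% one by one. Podocyte-like barcodes, from the filtering epithelium of the glomerulus, were higher in cells by 1.39 ± 0.927 points (0.620 one by one), and endothelial-like barcodes by 2.30 ± 1.80 points (5.39 with at most 20% mitochondrial UMIs, 0.988 without this filter). Intercalated-like cells of the collecting duct differed by 4.21 ± 4.89 points and principal-like cells by 0.573 ± 5.16 points, with no common direction over the 3 pairs. With at most 20% mitochondrial UMIs the intercalated difference turned to −0.322 points and the principal one to −1.60, then lower in cells in all 3 pairs, and without this filter the principal one was −0.218. Within the immune class, cells split into macrophage, T, dendritic, NK, neutrophil and B cell-like clusters. Macrophage-like barcodes took 52.4%, 44.5% and 31.1% of immune-like cells in control, 17 min and 27 min, and neutrophil-like barcodes took 1.99%, 5.31% and 8.44%. Immune-like nuclei, 89, 336 and 384 in number, formed macrophage-like and T cell-like clusters alone. An exact paired sign-flip test (two-sided) over 3 pairs cannot give a p below 0.25, which the classes with 3 pairs one way reached (adjusted p = 0.375 over 12 classes). Assigned one by one, the proximal difference was −4.64 points, with the 17 min pair at 1.965. The distal difference became −2.22 points at a cluster resolution of 0.5 and −3.70 in clusters made without tubular injury genes, and its 27 min pair then turned to 4.55 and 1.88, and to 1.69 with at most 20% mitochondrial UMIs.

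**Figure D1:**
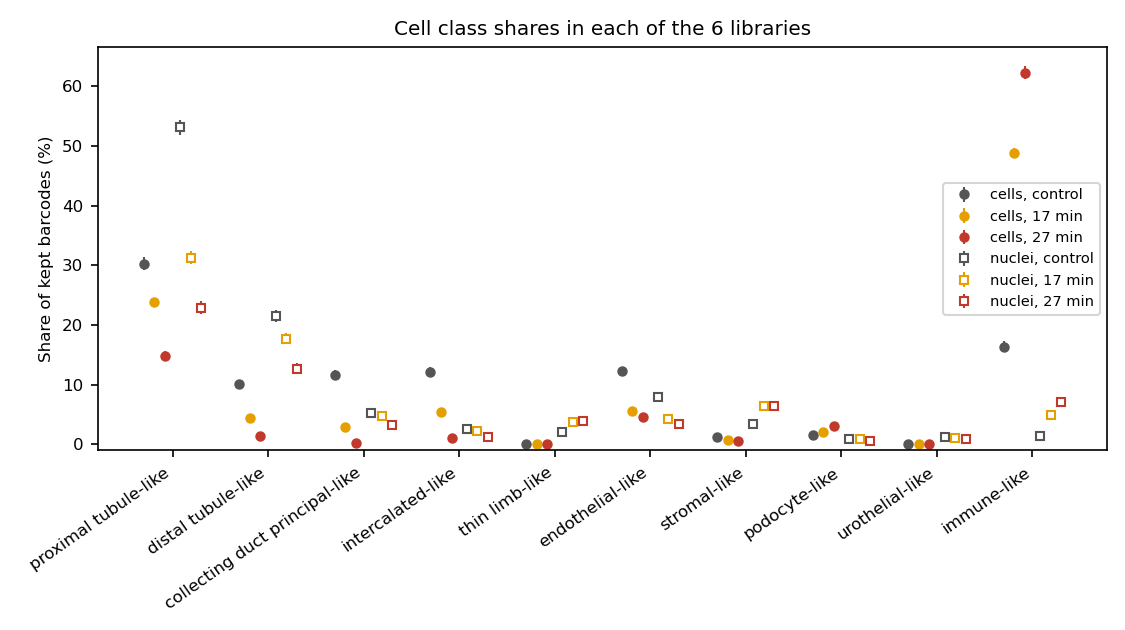
Share of barcodes in each class, in percent, for the 3 cell libraries (filled circles) and the 3 nuclei libraries (open squares), with exact binomial 95% intervals as bars. Immune-like shares reach 62.3% in cells and 7.16% in nuclei at 27 min, and proximal tubule-like shares are higher in nuclei in each injury state.

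The next question was how transcripts of one cell class differ between the preparations, tested across the 3 injury states with the injury state in the model (edgeR quasi-likelihood, n = 3 libraries per preparation). In proximal tubule-like barcodes, the epithelium that reabsorbs most filtered solutes, cells held far more Fos and Fosb, immediate early transcripts, which are made within minutes of a stimulus. Fos was 296-fold higher in cells (log2 fold change 8.21 ± 0.23 SE, adjusted p = 5.88e-10), and Fosb, with 0 UMIs in nuclei, at least 122-fold higher in each injury state against 3 UMIs per library. Cells were also higher in transcripts for ribosomal proteins and the respiratory chain by camera at its preset correlation (adjusted p = 0.336 for both lists with an estimated correlation). Nuclei were higher in Malat1, an RNA held in the nucleus (5.72-fold, log2 −2.51 ± 0.18, adjusted p = 9.49e-08). Of 13039 genes tested, 3245 were higher in cells and 3179 in nuclei at an adjusted p under 0.05 and a change of at least 2-fold.

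Immediate early genes were also higher in cells as a list, with 27 of 29 tested members up in cells, 0 down and a median log2 fold of 2.89 (camera adjusted p = 9.73e-09, and adjusted p = 0.336 with an estimated correlation). Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273) averaged 383 CPM (counts scaled to a common library total) in cells and 1.55 in nuclei. Its partner in the AP-1 transcription factor, Jun (chromosome 4, 95049034 to 95052222), was 23.1-fold higher in cells (4.53 ± 0.14). The stress-responsive factors Atf3 and Klf4 were higher by log2 6.13 ± 0.20 and 4.73 ± 0.16. Heat shock genes and chaperones had 15 of 18 members up and a median of 2.66 (camera adjusted p = 2.65e-05, and adjusted p = 0.359 with an estimated correlation). Hspa1a and Hspa1b, neighbouring genes for the inducible chaperone HSP70 whose reads are hard to tell apart, were higher by log2 5.50 ± 0.32 and 4.96 ± 0.31. Hspe1 and Hspd1, which encode the mitochondrial chaperonins and overlap head to head, were higher by 3.86 and 3.14.

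Transcripts of the energy and protein synthesis machinery were higher in cells. All 40 tested nuclear-encoded respiratory chain genes were up, with a median log2 of 3.36 (camera adjusted p = 4.78e-16, and adjusted p = 0.336 with an estimated correlation). Atp5c1, a subunit of ATP synthase, was 20.1-fold higher (4.33 ± 0.14) and Cox5a, a subunit of cytochrome c oxidase, 16.6-fold (4.06 ± 0.13). Cytosolic ribosomal protein genes had 57 of 60 members up and 1 down, with a median of 3.12 (camera adjusted p = 6.70e-17, and adjusted p = 0.336 with an estimated correlation), with Rps6 at 3.42 ± 0.12. All 13 mitochondrially encoded genes were up, with a median of 2.62 (camera adjusted p = 1.02e-05, and adjusted p = 0.377 with an estimated correlation), including mt-Nd2 at 2.89 and mt-Cytb at 2.79. Without the filter on mitochondrial UMIs, which acts on the same transcripts, this median was 1.81. Tpt1, a translation-associated protein of growing cells, and Mif, a secreted cytokine stored in the cytoplasm, were 20.2-fold and 24.3-fold higher in cells, and Bex4 was 22.7-fold higher.

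Metabolic lists leaned the same way. Fatty acid oxidation had 20 of 32 genes up and 0 down (median 1.40, camera adjusted p = 2.88e-06, and adjusted p = 0.336 with an estimated correlation), with the thiolase Acaa2 17.6-fold higher and Etfa, which passes electrons to the respiratory chain, 15.5-fold. Glycolysis had 8 of 14 up and 1 down (median 1.52, camera adjusted p = 0.0186, and adjusted p = 0.336 with an estimated correlation), with Pgk1 16.4-fold and Gapdh 15.5-fold higher. NRF2 targets, the oxidant defence genes, had 14 of 18 up (median 2.39, camera adjusted p = 1.38e-05, and adjusted p = 0.336 with an estimated correlation), with Taldo1 at 3.81 and catalase (Cat) at 2.93. Proximal tubule transport and metabolism genes had 22 of 52 up and 2 down (median 0.70, camera adjusted p = 0.000913, and adjusted p = 0.336 with an estimated correlation). Fbp1 of gluconeogenesis was higher by 3.81 ± 0.13, and Ttc36 and Akr1c21 by 3.75 and 3.58. Without TMM scaling this list's median turned to −0.10.

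On the nuclear side, 4 of 6 nuclear-retained RNAs were up in nuclei and 0 in cells (median −2.13, camera adjusted p = 0.0103, and adjusted p = 0.336 with an estimated correlation). Malat1 (ENSMUSG00000092341, chromosome 19, 5795690 to 5802672) took 31135 CPM in cells and 177773 in nuclei. Its neighbour Neat1, the scaffold of paraspeckles, was lower in cells by log2 −2.30 ± 0.13, Snhg11 by −2.18 and Kcnq1ot1, the antisense RNA of the Kcnq1 locus, by −2.08. Among the other RNAs highest in nuclei were Snhg20 (−2.78), the splicing kinase gene Prpf4b (−2.67), the poly(A)-binding protein gene Pabpn1 (−2.55), Rnf24 (−2.70), Dzip1l (−2.54) and AI480526 (−2.59). AC149090.1, which has no model in the annotation, was at −2.61, and Methig1, a relative of the Mettl7a genes with which reads can be shared, at −2.80. Long genes rich in pre-mRNA had 3 of 18 up in cells and 9 up in nuclei (median −0.91, camera adjusted p = 0.0947), with Wwox at −1.53, Foxp1 at −1.24 and Macrod2 at 1.19.

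Transcripts of other cell types differed too. Mgp, a calcification inhibitor and fibroblast marker (ENSMUSG00000030218, chromosome 6, 136872435 to 136875823), was 35.9-fold higher in nuclei (log2 −5.16 ± 0.24, adjusted p = 1.89e-09), at 3.08 CPM in cells and 119 in nuclei. Umod, the uromodulin gene of the thick ascending limb, was 9.53-fold higher in nuclei. Extracellular matrix genes had 10 of 21 up in nuclei and 0 in cells (median −1.08, camera adjusted p = 0.0513), with the collagen gene Col1a2 at −4.51 ± 0.29 and fibronectin (Fn1) at −2.84 ± 0.25. Col3a1, another collagen gene, stood at 0.163 CPM in cells and 35.9 in nuclei. Immune markers had 13 of 14 up in cells and 1 down (median 2.26, camera adjusted p = 0.00183, and adjusted p = 0.336 with an estimated correlation), with Cd52 at 2.63 and Tyrobp at 2.26. Class II antigen presentation had 7 of 8 up in cells (median 2.01, camera adjusted p = 0.0140, and adjusted p = 0.336 with an estimated correlation), with H2-Eb1 at 2.37 and the invariant chain gene Cd74 at 2.25. Chemokines and inflammatory genes had 10 of 24 up and 5 down (median 0.59, camera adjusted p = 0.272), with the cytokine gene Il1b at 21.6 CPM in cells and 0.272 in nuclei and the signalling gene Nfkb1 at −1.47. Haemoglobin and red cell genes had 4 of 4 up (median 2.30, camera adjusted p = 0.370), with medians by state of 2.59 in control, 1.82 at 17 min and −0.78 at 27 min, and with Hba-a2 and its near-identical copy Hba-a1 at 3.04 and 2.37.

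In the other lists of this class, members went both ways. Tubular injury genes had 12 of 40 up in cells and 12 in nuclei, with a median of −0.21 and a mean of −0.10, while the camera direction was up (adjusted p = 0.508). By state the median was 0.66 in control, −0.41 at 17 min and −0.42 at 27 min. The keratin gene Krt8 was higher in cells by 2.87 and Havcr1, which encodes the injury marker KIM-1, was 6.58-fold higher in nuclei (−2.72 ± 0.19, adjusted p = 5.23e-08). Havcr1 had 3 UMIs in each control library, and 2 of the 3 injury states went this way. Hypoxia response genes had 8 of 18 up and 2 down (median 0.97, camera adjusted p = 0.0947), with the mitophagy gene Bnip3 at 3.42 and Vegfa at −1.30. Cholesterol synthesis had 8 of 19 up and 1 down (0.78, adjusted p = 0.0746 by camera), p53 targets 5 of 18 up and 2 down (0.48, adjusted p = 0.190) and interferon response 8 of 23 up and 3 down (0.20, adjusted p = 0.515). Cell cycle genes had 5 of 24 up and 5 down (median 0.16, camera adjusted p = 0.508), or 5 and 4 adjusted over the list alone. For the other 21 lists of this class, counts adjusted over the list alone were the same as those over all genes.

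**Figure D2:**
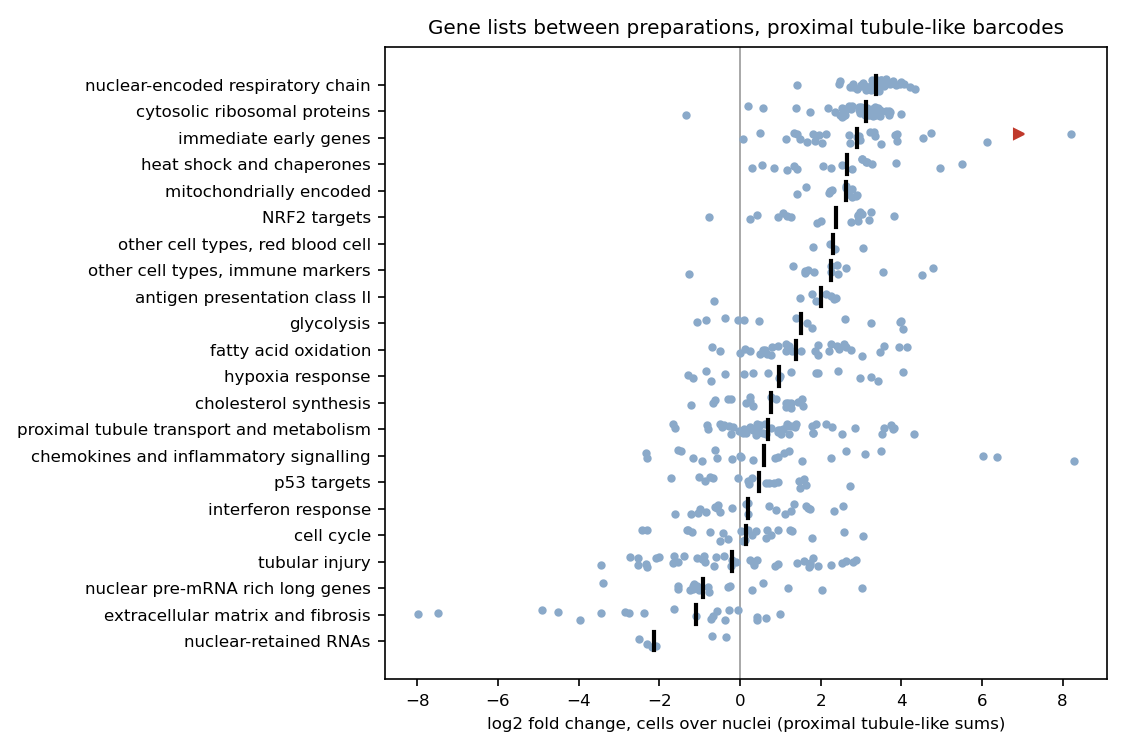
Log2 fold change of cells over nuclei in proximal tubule-like barcodes for each member of the 22 gene lists (dots), with each list's median as a black tick, and Fosb at its lower bound as a red triangle. Respiratory chain and ribosomal protein genes sit to the right with medians of 3.36 and 3.12, and nuclear-retained RNAs to the left with a median of −2.13.

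These folds are relative to the scaling. Without TMM scaling the median of all tested genes moved from −0.09 to −0.89 in proximal tubule-like barcodes, a shift of −0.80, and the split became 1702 genes higher in cells and 6072 in nuclei. With sums thinned to the smallest library it was 2116 and 1617. Different nuclei clusters held the largest part of the class, cluster 2 with 1306 of 3313 barcodes in control and cluster 4 with 500 of 1228 at 27 min.

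Other classes were tested in the same way. Immediate early genes were higher in cells of the endothelial-like (median 1.88, 22 of 26 up, camera adjusted p = 1.07e-07, and adjusted p = 0.320 with an estimated correlation), immune-like (3.44, 29 of 31 up, adjusted p = 9.24e-10, and adjusted p = 0.284 with an estimated correlation) and intercalated-like class (2.69, 21 of 25 up, adjusted p = 2.82e-06, and adjusted p = 0.415 with an estimated correlation). In distal tubule-like barcodes the list had 4 of 25 up and 2 down, with a median of −0.24, a mean of 0.02 and camera adjusted p = 0.942. That distal value rested on the clusters, with medians of 0.31 at a resolution of 2, 1.73 with barcodes assigned one by one and 3.15 with at most 20% mitochondrial UMIs. Of the 1056 distal tubule-like cells behind the 3.15, 731 were injured tubule-like and 240 distal tubule-like in the main clusters. The main distal class also joined partly different segments in cells and nuclei. Its cell clusters were named thick ascending limb-like (730) and connecting tubule-like (702). Its nuclei clusters were named thick ascending limb-like (1384 and 946) and distal convoluted tubule-like (884), the last with 5 connecting tubule markers counted as well. Mitochondrially encoded genes were up in cells of the distal (13 of 13, median 2.24, camera adjusted p = 2.14e-07, and adjusted p = 0.546 with an estimated correlation) and intercalated class (12 of 13, 2.06, adjusted p = 5.64e-06, and adjusted p = 0.415 with an estimated correlation). They had 0 of 13 members up in endothelial-like (0.19, adjusted p = 0.438) and immune-like barcodes (0.47, adjusted p = 0.137). Whether classes differed from each other was not tested. For the lists named in these classes, counts adjusted over the list alone were the same.

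Transcripts of proximal tubule transport were higher in nuclei of every other class tested. They had 26 of 48 members up in nuclei in distal tubule-like (median −1.25, camera adjusted p = 0.00543, and adjusted p = 0.727 with an estimated correlation), 38 of 50 in endothelial-like (−2.47, adjusted p = 8.14e-11, and adjusted p = 0.485 with an estimated correlation), 39 of 51 in immune-like (−2.25, adjusted p = 5.64e-12, and adjusted p = 0.347 with an estimated correlation) and 37 of 42 in intercalated-like barcodes (−2.99, adjusted p = 3.54e-09, and adjusted p = 0.415 with an estimated correlation). As a measure of background, proximal tubule marker genes took 0.148%, 0.154% and 0.0507% of UMIs in immune-like cells of control, 17 min and 27 min, and 2.20%, 1.09% and 0.784% in immune-like nuclei. In proximal tubule-like barcodes they took 5.61%, 6.15% and 4.19% in cells and 3.48%, 2.86% and 2.58% in nuclei. Immune markers took 0.0103%, 0.0371% and 0.0961% of UMIs in proximal tubule-like cells and 0.00639%, 0.0235% and 0.0354% in nuclei.

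The counts of genes higher in cells and in nuclei were 2331 and 2982 of 11336 in distal tubule-like, 2295 and 2143 of 9748 in endothelial-like, 3585 and 3001 of 12545 in immune-like and 2090 and 1843 of 7937 in intercalated-like barcodes. Without TMM they were 1628 and 4313, 1931 and 2618, 1338 and 6583, and 1360 and 2934. The median of all genes then shifted by −0.41, −0.19, −1.23 and −0.53. With sums thinned to the smallest library they were 182 and 35, 577 and 416, 2 and 5, and 0 and 2. Leaving out 1 library takes its whole pair out of the comparison, since the library left alone in that state is fitted exactly by the injury term. Without 1 library, the immune count in nuclei went from 3001 to 1568 (17 min nuclei), 1821 (17 min cells) or 1884 (27 min nuclei). The intercalated count in nuclei went from 1843 to 1032 (control cells), 1075 (17 min cells), 1150 (17 min nuclei) or 1178 (control nuclei). Cells of the immune class held dendritic, NK, neutrophil and B cell-like clusters that nuclei lacked. Distal tubule-like barcodes were mostly cluster 20 in control cells (432 of 682) and cluster 17 at 27 min (66 of 106), and mostly cluster 3 in control nuclei and cluster 8 at 27 min. Cell cluster 20, named connecting tubule-like, counted 6 markers of that type and 7 of principal cells.

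Summed over all barcodes, immune genes had the largest list medians of the 22. Immune markers had 16 of 16 members up in cells with a median log2 of 6.04 (camera adjusted p = 3.39e-08, and adjusted p = 0.336 with an estimated correlation), and class II antigen presentation 8 of 8 with 5.62 (adjusted p = 2.70e-05, and adjusted p = 0.359 with an estimated correlation). Immune markers took 0.328%, 1.59% and 2.25% of UMIs in control, 17 min and 27 min cells and 0.00910%, 0.0517% and 0.0905% in nuclei. Ribosomal protein genes had 58 of 60 up (3.53, adjusted p = 1.86e-16, and adjusted p = 0.451 with an estimated correlation), cell cycle genes 23 of 32 (1.498, adjusted p = 5.40e-05, and adjusted p = 0.523 with an estimated correlation, with 1 down adjusted over the list alone) and interferon response genes 18 of 25 (1.66, adjusted p = 1.05e-05, and adjusted p = 0.451 with an estimated correlation). Of 16973 genes, 4518 were higher in cells and 3916 in nuclei. Without TMM these were 2570 and 7142 (shift of the median gene −0.78), and without 17 min nuclei the count in nuclei was 2205.

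The last question was how kidneys of the injury states differed from control and whether both preparations show it. There was 1 library per group, so no comparison of injury states was tested. Each value sets an injured library against the control library of its own preparation. Intervals of folds and shares cover counting error only, and those of list medians the spread over member genes. No spread between animals is known. Among the classes, immune-like barcodes were higher at 27 min than in control by 46.0 points in cells and 5.74 in nuclei (9.60 with barcodes assigned one by one). Proximal tubule-like barcodes were lower by −15.4 points in cells, from 30.2% to 14.9% (14.1 to 15.7), and by −30.3 in nuclei, from 53.2% (51.9 to 54.4) to 22.9% (21.8 to 24.1). In cells the higher immune-like share leaves less for the other classes, so lower shares there do not show a loss of those cells. Distal tubule-like barcodes differed by −8.60 and −8.79 points, and endothelial-like by −7.59 and −4.45. Principal-like and intercalated-like barcodes differed by −11.5 and −11.1 points in cells and by −1.97 and −1.47 in nuclei. Stromal-like barcodes differed by −0.70 points in cells and 3.10 in nuclei, but the value in cells was 0.0983 without the mitochondrial filter, 0.160 with at most 20% mitochondrial UMIs and 0.335 with barcodes assigned one by one, where nuclei gave 9.55. An unnamed nuclei cluster held 0.160%, 11.5% and 21.7% of nuclei in control, 17 min and 27 min. It counted 2 injured tubule markers, Havcr1 and Dcdc2a. The lower proximal share in nuclei was therefore not told apart from barcodes changing class. In clusters made without tubular injury genes, chosen after seeing the data, injured tubule-like barcodes were higher at 27 min by 1.41 points in cells and 31.7 in nuclei. These clusters were still named from injured tubule markers such as Havcr1, which was itself higher at 27 min, so this rise is partly built in. The mitochondrial filter and the clusters moved several of these differences: with at most 20% mitochondrial UMIs the distal ones were −2.91 and −17.7 points and the proximal, endothelial, principal and intercalated ones in cells −23.4, −14.4, −2.82 and −2.81, and without this filter the proximal, distal and endothelial ones in cells were −9.01, −13.4 and −4.27. The distal ones were −5.22 and −17.7 at a resolution of 0.5.

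In proximal tubule-like barcodes at 27 min, tubular injury genes were higher in both preparations, with a median log2 fold of 2.02 (order-statistic 95% interval over members 1.11 to 2.75) in cells and 2.86 (2.08 to 3.85) in nuclei. Of 31 compared members, 22 were at least 2-fold higher in both. Fgg, the fibrinogen gamma chain gene (ENSMUSG00000033860, chromosome 3, 83007724 to 83015049), was 24.0-fold higher in cells (exact interval 19.6 to 29.6) and 50.7-fold in nuclei (31.0 to 88.5). Havcr1 (ENSMUSG00000040405, chromosome 11, 46735080 to 46779578) was 49.8-fold higher in cells (16.6 to 245) and 348-fold in nuclei (118 to 1696), from 3 UMIs in each control. C3, the central complement gene, was 12.0-fold (9.63 to 15.1) and 26.7-fold (18.6 to 39.4) higher. The organic anion transporter gene Slc22a7 (ENSMUSG00000067144, chromosome 17, 46432183 to 46438457) was at 0.0388 times control in cells (0.0277 to 0.0529) and 0.0729 in nuclei (0.0470 to 0.108).

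Many of these genes also differed from control at 17 min. Both states are set against the same control library of each preparation, so their folds are not independent. Tubular injury medians were 1.01 (0.49 to 1.31) in cells and 2.27 (1.64 to 2.89) in nuclei, and for 27 min over 17 min they were 0.66 and 0.62. Fgg stood at log2 2.19 in cells and 2.53 in nuclei at 17 min, Havcr1 at 2.54 and 5.84, and C3 at 1.64 and 4.41. Slc22a7 stood at −2.24 and −1.92, the related transporter gene Slc22a19 at −2.11 and −2.02, and Cyp7b1, an oxysterol hydroxylase gene, at −2.61 and −0.75. At 27 min Slc22a19 was at −3.77 and −2.86, and Cyp7b1 at −4.75 and −2.26. Wfdc15b stood at 0.05 and −0.39 at 17 min and at −2.48 and −2.63 at 27 min. It was among the top 10 genes of the thick ascending limb-like cell cluster. Background from distal tubule-like barcodes was therefore not told apart from a change in the proximal class. Other genes far above control at 27 min were Ctss, the lysosomal protease cathepsin S (3.20 in cells and 3.52 in nuclei), complement factor I (Cfi, 21.3-fold, 12.9 to 37.9, and 54.4-fold, 17.5 to 274, from 3 UMIs in control nuclei), the proteoglycan gene Gpc3 (3.19 and 4.23) and the actin regulator Tmsb10 (3.13 and 3.87). Below control were Serpina1d (−4.80 and −2.39), whose paralogs share sequence, Kif20b (−2.32 and −2.67), Acsm3 (−2.22 and −2.28), Myo5a (−2.53 and −2.34) and Rnf24 (−2.56 and −2.21). Several of these lowered genes were among the top 10 of proximal tubule-like clusters that shrank. Nuclei cluster 5 (Slc22a7, Slc22a19, Cyp7b1, Myo5a and Rnf24) held 653 of 3313 nuclei of the class in control and 84 of 1228 at 27 min. Cell cluster 31 (Slc22a7, Cyp7b1 and Serpina1d) held 73 of 2048 cells and 4 of 1072. Lower levels per cell were not told apart from this change in makeup.

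Inflammatory lists were higher too, but they share members with the injury list, so moving together is partly built in. Ccl2, Cxcl1, Cxcl2, Vcam1 and C3 are in both the tubular injury and the chemokine list. Socs3 is also in the immediate early list and Cdkn1a in the p53 list. Cd74 is in both the class II and the immune marker list. Chemokines and inflammatory genes had medians of 1.90 (1.14 to 3.43) in cells and 1.93 (0.95 to 4.48) in nuclei, with 9 of 13 members at least 2-fold higher in both. Ccl2, which draws in monocytes, was 142-fold higher in cells (24.9 to 5645) and 256-fold in nuclei (44.4 to 10233), from 1 UMI in each control, and Cxcl10 was 50.9-fold and 7.10-fold higher. Immediate early genes had medians of 1.40 (0.81 to 1.85) and 1.33 (0.95 to 1.94), with 11 of 20 members higher in both. Junb was at 2.36 and 1.69, Klf6 at 2.51 and 1.93, and Socs3, a brake on cytokine signalling, 36.7-fold (18.3 to 86.0) and 85.2-fold higher (13.9 to 3503), from 8 and 1 control UMIs. With injured tubule-like barcodes added to the class, medians in nuclei were 3.91 for chemokines and 2.82 for immediate early genes. Class II genes had medians of 3.03 (2.23 to 3.46) and 2.96 (1.97 to 3.52), all 8 higher in both, with Cd74 11.2-fold (10.3 to 12.3) and 10.3-fold (8.13 to 13.0). With called doublets kept the class II median in cells was 1.98, and with a pseudocount of 10 CPM the medians were 2.24 and 1.51. Immune markers such as C1qa (2.97 and 3.46) had medians of 2.93 and 2.97, and the share of immune-like barcodes was higher in the same libraries. Interferon response medians were 1.08 and 1.42, with 5 of 11 higher in both and Ifitm3 at 2.46 and 2.15, and p53 targets 0.28 and 0.36, with 4 of 14 higher in both and the cell cycle inhibitor gene Cdkn1a at 2.66 and 2.08.

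Proximal tubule transport medians at 27 min were −0.17 in cells and −0.25 in nuclei, with 1 of 52 members at least 2-fold higher and 5 lower in both, among them Slco1a1 (−1.70 and −1.78) and the tyrosine catabolism gene Hpd (−2.17 and −1.63). These medians leave out injured tubule-like and unnamed barcodes. With injured tubule-like ones added they were −0.38 and −1.06. With the unnamed nuclei cluster too, an alternative chosen after seeing the data, they were −0.38 and −1.29. In cells the injured tubule-like cluster also carried principal and connecting tubule markers. Heat shock genes had a median of 0.36 (0.02 to 0.81) in cells and −0.69 (−1.20 to −0.29) in nuclei, while the small heat shock gene Hspb1 was at 0.97 and 3.32. Extracellular matrix medians were 0.82 and 1.62, with 2 of 9 at least 2-fold higher in both and Sparc at 2.33 and 2.51. Medians in cells and nuclei were −0.02 and −0.33 for fatty acid oxidation, −0.06 and 0.17 for glycolysis, −0.06 and −0.25 for NRF2 targets, 0.26 and 0.13 for cell cycle, and −0.06 and 0.21 for hypoxia response. They were 0.18 and 0.21 for cholesterol synthesis, −0.04 and 0.05 for long genes, −0.08 and −0.22 for nuclear-retained RNAs, 0.28 and 0.52 for ribosomal proteins, 0.01 and 0.15 for mitochondrially encoded genes, and −0.20 and −0.16 for the respiratory chain. Red cell genes were at −3.86 and −0.70. The sign of the mitochondrially encoded median in nuclei turned to −0.69 with called doublets kept and to −0.45 with at most 20% mitochondrial UMIs.

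**Figure D3:**
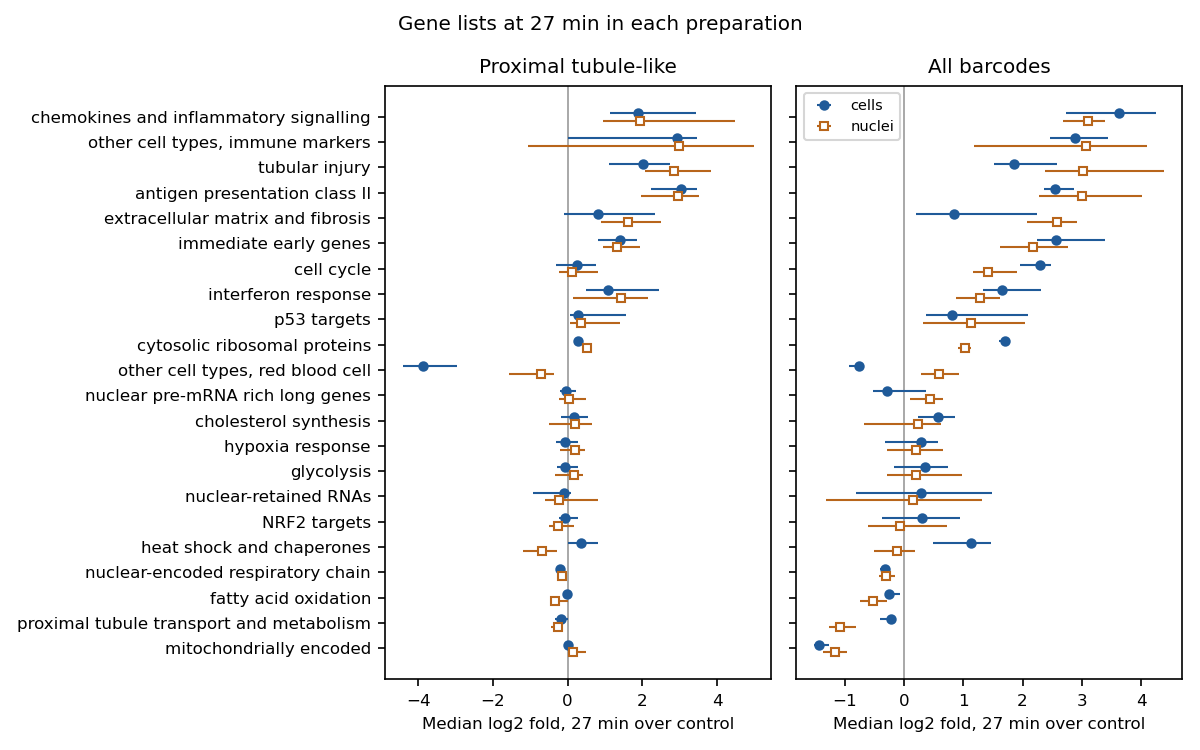
Median log2 fold of 27 min over control for each gene list in cells and in nuclei, with the order-statistic interval of the median over member genes as bars, for proximal tubule-like barcodes and for all barcodes. In proximal tubule-like barcodes the class II and tubular injury lists lie far right in both preparations, at 3.03 and 2.02 in cells and 2.96 and 2.86 in nuclei.

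Across genes, the folds of cells and nuclei went together in part, with a Spearman rho of 0.353 over 10826 genes at 17 min and 0.458 over 10428 genes at 27 min. Genes are not independent replicates. With injured tubule-like barcodes added to the class, rho at 27 min was 0.653 and the tubular injury median in nuclei 4.04. The added barcodes were unlike in cells and nuclei. Their cell cluster counted 6 injured tubule markers without Havcr1, beside 5 of principal and 3 of connecting tubule cells. Each of their nuclei clusters counted Havcr1, Vcam1 and Cd44. Control and 27 min held 249 and 487 such cells, and 32 and 842 such nuclei. With barcodes thinned to 500 UMIs rho was 0.293 and the tubular injury medians 1.37 and 2.07, and rho was 0.353 with barcodes weighted equally and 0.322 with at most 20% mitochondrial UMIs. With a pseudocount of 10 CPM in place of 1 the medians were 0.83 and 1.72 for tubular injury and 1.02 and 1.30 for chemokines.

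Over all barcodes, chemokine and cell cycle genes were higher at 27 min than in control in both preparations. Cxcl2, which attracts neutrophils, was 47.1-fold higher in cells and 221-fold in nuclei, Ccl2 54.9-fold (48.9 to 61.9) and 106-fold (75.2 to 156), and Lyz2, a lysozyme gene of myeloid cells, 11.7-fold and 68.0-fold. Chemokine medians were 3.62 and 3.10, with 21 of 25 members at least 2-fold higher in both. Cell cycle genes had medians of 2.29 and 1.42, with 24 of 31 higher in both and Top2a, a topoisomerase of dividing cells, 9.38-fold and 7.82-fold higher. Matrix genes had medians of 0.85 (0.20 to 2.24) in cells and 2.58 (2.07 to 2.92) in nuclei. Of 25 members 11 were at least 2-fold higher and 2 lower in cells, 24 were higher in nuclei and 11 in both, with Fn1, the fibronectin gene, 18.6-fold and 26.4-fold and Col1a1 59.8-fold and 47.9-fold higher. The stromal-like share differed by −0.70 points in cells and 3.10 in nuclei between the same libraries. At 17 min Col1a1 stood at log2 1.34 in cells and 4.48 in nuclei. Tubular injury medians were 1.85 (1.51 to 2.59) and 3.02 (2.38 to 4.40), with 30 of 40 higher in both, and immediate early medians 2.56 and 2.18, with 26 of 30. With a pseudocount of 10 CPM medians were 0.26 and 1.49 for matrix, 1.02 and 0.56 for cell cycle, 2.26 and 1.85 for chemokine, 1.18 and 2.18 for tubular injury and 2.37 and 1.45 for immediate early genes. With mitochondrially encoded genes left out, medians in cells were 3.01 for chemokine, 1.25 for tubular injury and 1.90 for immediate early genes. The immune-like share of barcodes was higher in the same libraries, 62.3% of cells and 7.16% of nuclei at 27 min.

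Among the genes furthest below control over all barcodes at 27 min were Egf and Calb1. Egf, the growth factor gene of the thick ascending limb, was at log2 −3.76 in cells and −3.41 in nuclei, with −0.59 and −1.84 at 17 min. Calb1, a calcium-binding protein gene of the connecting tubule, was at −3.40 and −3.16, with −0.72 and −0.91 at 17 min. Insrr was at −4.03 and −2.35, Abca13 at −2.95 and −2.56, and Slc22a7 at −3.65 and −4.06. Egf and Calb1 are distal tubule markers and Insrr an intercalated one. From control to 27 min the distal tubule-like share of kept barcodes went from 10.1% to 1.47% in cells and from 21.5% to 12.7% in nuclei. The intercalated-like share went from 12.2% to 1.08% and from 2.66% to 1.19%. Lower levels per cell were not told apart from these lower shares. Proximal tubule transport medians were −0.21 and −1.08, fatty acid oxidation −0.25 and −0.52, and the respiratory chain −0.32 and −0.30. Mitochondrially encoded genes had medians of −1.44 (−1.52 to −1.27) in cells and −1.16 in nuclei, and among barcodes that pass the filters, an alternative chosen after seeing the data, the nuclei median was 0.13. Ribosomal protein medians were 1.71 and 1.04. With mitochondrially encoded genes left out the medians in cells became −0.88 for proximal tubule transport, −0.91 for fatty acid oxidation, −0.99 for the respiratory chain and 1.04 for ribosomal proteins, and with TMM within preparations −0.53, −0.56, −0.64 and 1.39.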

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

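The tests of damaged distal cells, of free RNA as a source of immediate early transcripts and of other splits of the libraries were chosen after the result was seen; the other tests in this part were planned before it.

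Several lists had opposite signs in 2 groups under the same comparison, and none of these differences was tested. In proximal tubule-like barcodes, 17 min and 27 min over control, glycolysis was at −0.052 and −0.059 (median log2) in cells and at 0.10 and 0.17 in nuclei, and hypoxia response at −0.024 and −0.060 in cells and at 0.065 and 0.21 in nuclei. Over all barcodes, heat shock genes were at 0.63 and 1.13 in cells and at −0.37 and −0.12 in nuclei, and NRF2 targets at 0.18 and 0.30 in cells and at −0.13 and −0.064 in nuclei.

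For cells over nuclei in control, 17 min and 27 min, proximal tubule transport genes were at 0.57, 0.85 and 0.78 in proximal tubule-like barcodes. They were at −1.38, −0.80 and −1.28 in distal tubule-like, −2.73, −1.71 and −2.60 in endothelial-like, −1.94, −1.65 and −2.38 in immune-like and −3.22, −2.34 and −1.71 in intercalated-like barcodes. Fatty acid oxidation genes were at 1.02, 1.58 and 1.56 in proximal tubule-like, 0.44, 1.16 and 1.13 in distal tubule-like and 0.99, 1.75 and 0.79 in intercalated-like barcodes, against −0.62, −0.021 and −0.12 in endothelial-like ones. Matrix genes were at −0.19, −0.93 and −1.36 in proximal tubule-like and at 0.89, 0.22 and 0.91 in endothelial-like barcodes.

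Immediate early genes were higher in cells than in nuclei in proximal tubule-like barcodes (median 2.89), while distal tubule-like barcodes gave −0.24, and the median proximal over distal ratio of their levels was 2.26 (1.46 to 3.21) in cells and 0.387 (0.196 to 0.527) in nuclei. Damage to distal cells stays open. The distal tubule-like barcodes with at most 20% mitochondrial UMIs gave −0.19 (95% interval −0.84 to 0.50), but held 40 cells at 27 min, under the minimum of 50. Control and 17 min met this minimum and gave medians of 0 and 0.13, against 1.81 and 2.34 in proximal tubule-like barcodes. The limit thus did not bring distal medians to the proximal level there, but single states had no interval. Clustering anew at that limit gave 3.15, with 731 of its 1056 distal cells from the injured tubule-like class. That value rests mostly on cells outside the main distal class. Clusters drawn by immediate early genes may have moved activated distal cells out of the class. Clusters made without mitochondrial, ribosomal and immediate early genes gave 0.61 (0.065 to 1.01), between the 2 classes. These groups were removed together, so the part of immediate early genes stays open. Free RNA in the cell libraries stays open too, since a share of it could remain under the 2.26. Alone it would give a ratio of 1 in cells only if it took the same share of UMIs in both classes, which was not measured. A biological difference between the segments was not tested. Distal tubule-like cells and nuclei also came from clusters named after partly different segments, and the part of this in the distal value was not tested.

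Class II genes were higher in injured than in control proximal tubule-like barcodes in both preparations. Free RNA or doublets from immune cells remain a candidate source: in that case class II genes and other immune markers would reach the same percent of their immune-like level, and the lowest of the 4 injured libraries' ratios was 1.05 (17 min cells). The others were 1.82, 1.89 and 2.09, against 1.08 and 1.10 in the control libraries, and 3 of the 4 lay under 2. With called doublets kept the class II median at 27 min in cells went from 3.03 to 1.98 and that of immune markers from 2.93 to 1.86. A gain of class II expression in the tubule itself was not told apart from this.

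Genes higher in nuclei of proximal tubule-like barcodes had a median length of 26.4 kb, against 13.0 kb for genes higher in cells and 22.5 kb for all tested genes with a model. The prediction for unspliced RNA of long introns, a negative tie of fold to gene length that stays given exon length, was not met. The rank correlation of fold and gene length across genes, −0.20, became 0.060 given exon length, with −0.36 for exon length. This cannot exclude unspliced RNA, since the labels do not state whether intronic reads were counted. Other splits of the 6 libraries into 3 and 3 called 0 genes at most, and the real split, 1 of 10, called 8434 over all barcodes, 6424 in proximal tubule-like, 5313 in distal tubule-like, 4438 in endothelial-like, 6586 in immune-like and 3933 in intercalated-like barcodes. The splits are too few for a share under 0.05. Each other split also mixes cells and nuclei in both groups, so the preparation difference enters its residual spread and keeps calls low. The 0 is therefore no separate support for the real split.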

How the results depend on the processing

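The tests with doublets at the automatic threshold, clusters made without tubular injury genes, barcodes that pass the filters, and proximal, injured and unnamed nuclei clusters together were chosen after the data were seen; the others were planned. Each value was recomputed under each alternative that applies to it. Here the same means within 1.5 times for a count, inside the interval over members for a list median, within counting error for rho and for a share by injury, within 1 SD over the 3 libraries or pairs for other shares, within 1 log2 unit for an injury fold of a gene, and on the same side of the threshold for a tested gene, so it does not mean unchanged. Of these recomputed values, among those that answer a comparison 747 stayed the same, 162 moved and 7 changed sign, and among single genes and lists 7499 stayed the same, 294 moved, 45 lost and 19 gained their call, and 5 changed sign. DESeq2 gave 4516 and 3752 genes over all barcodes, 3239 and 2743 in proximal tubule-like, 2242 and 2152 in distal, 1929 and 1733 in endothelial, 3166 and 2826 in immune and 1842 and 1411 in intercalated ones. Unless construction shows it, the cause was not tested. Thinning sums to the smallest library left 2116 and 1617 proximal tubule-like genes, 217 distal, 993 endothelial, 7 immune and 2 intercalated ones, with medians in proximal tubule-like barcodes of 2.94 for ribosomal proteins and 3.20 for the respiratory chain. Injury folds had no replicate check. In values below, lists are medians (log2), injury means 27 min over control, and shares are percentage points.

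Leaving out 1 library gave 3854 to 5157 genes higher in cells and 2205 to 4195 in nuclei over all barcodes, 3173 to 3379 and 2763 to 3283 in proximal tubule-like barcodes, and 4574 to 5352 distal, 3887 to 4578 endothelial, 4522 to 7012 immune and 2728 to 4190 intercalated genes. It gave 12 to 13 lists past camera. Medians ran from 2.50 to 2.77 for mitochondrially encoded genes, 3.05 to 3.24 for ribosomal proteins, 3.30 to 3.44 for the respiratory chain, 2.72 to 2.96 for immediate early genes, 2.68 to 2.77 for heat shock, −2.19 to −2.04 for nuclear-retained RNAs and 0.62 to 0.81 for proximal tubule transport, and from −0.52 to 0.04 for immediate early genes in distal tubule-like barcodes. A lone library left in a state is fitted exactly by the injury term, so leaving out 1 library takes its whole pair out of the preparation comparison.

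For preparations, no TMM gave 2570 and 7142 genes over all barcodes and 1702 and 6072 in proximal tubule-like ones, with 1.83 for mitochondrially encoded genes, 2.32 for ribosomal proteins, 2.56 for the respiratory chain, −2.93 for nuclear-retained RNAs, −0.10 for proximal tubule transport (sign changed) and −0.64 for distal immediate early genes. Any fold change gave 5074 genes higher in proximal tubule-like nuclei. Mitochondrially encoded genes were at 1.81 without the mitochondrial filter, 2.95 with doublets kept and 2.96 with the automatic threshold. Ribosomal proteins and the respiratory chain were at 2.82 and 3.11 without the mitochondrial filter and at 3.34 and 3.58 with at most 20% mitochondrial UMIs. Distal immediate early genes were at 3.15 with at most 20%, 2.44 at resolution 0.5, 0.31 at resolution 2, 1.73 one by one, 1.25 with doublets kept, 0.48 with the automatic threshold, 0.61 without mitochondrial, ribosomal and immediate early genes and 1.19 without tubular injury genes. Hbb-bs was at −0.37 with barcodes assigned one by one (sign changed). At most 20% left intercalated-like barcodes under the minimum, so no value was made.

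For shares of cells over nuclei, distal was −7.45 without the mitochondrial filter, −6.39 at most 20%, −9.38 at resolution 2, −2.22 at resolution 0.5, −8.95 one by one, −6.32 without mitochondrial, ribosomal and immediate early genes and −3.70 without tubular injury genes. Endothelial was 5.39 at most 20%, and stromal −6.79 one by one. For injury, proximal shares were −9.01 in cells without the mitochondrial filter, −23.4 in cells and −32.0 in nuclei at most 20%, −13.0 and −27.3 one by one, and in nuclei −34.3 with the automatic threshold, −34.9 at resolution 2, −33.7 at 0.5, −36.5 without mitochondrial, ribosomal and immediate early genes and −36.9 without tubular injury genes. Distal shares were −13.4 and −6.99 without the filter, −2.91 and −17.7 at most 20%, −5.22 and −17.7 at resolution 0.5, −7.19 and −15.1 one by one, −7.73 and −17.5 without tubular injury genes and, in nuclei, −17.6 without mitochondrial, ribosomal and immediate early genes. Endothelial shares in cells were −4.27 without the filter and −14.4 at most 20%, and in nuclei −3.47 one by one. Immune shares were 44.4 in cells at most 20% and 9.60 in nuclei one by one.

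In proximal tubule-like injury folds, rho was 0.482 without the mitochondrial filter, 0.447 with doublets kept, 0.432 with the automatic threshold, 0.322 at most 20%, 0.420 at resolution 2, 0.441 at 0.5, 0.406 one by one, 0.403 without mitochondrial, ribosomal and immediate early genes, 0.410 without tubular injury genes, 0.353 weighted equally, 0.480 at 100 UMIs, 0.293 thinned to 500 UMIs (0 barcodes left out), 0.653 with injured barcodes and 0.670 with the unnamed cluster too. Mitochondrially encoded genes in nuclei changed sign to −0.69 with doublets kept, −0.58 with the automatic threshold, −0.45 at most 20%, −0.23 weighted equally and −0.20 thinned, and were at 0.67 with injured barcodes. In cells they were at −0.14 without the filter, −0.10 weighted equally, −0.083 thinned, −0.033 with TMM within preparations, and −0.047 with injured barcodes, with and without the unnamed cluster. The respiratory chain in nuclei changed sign to 0.10 without the filter. Ribosomal proteins were at 0.35 and 0.75 without the filter, 0.35 and 0.89 with injured barcodes, 0.35 and 0.80 with the unnamed cluster too, in nuclei 0.46 without mitochondrial, ribosomal and immediate early genes, and in cells 0.30 with doublets kept or mitochondrial genes left out, 0.29 with the automatic threshold, 0.17 at most 20%, 0.21 weighted equally or thinned and 0.24 with TMM within preparations. Class II in cells was at 1.98 with doublets kept. Tubular injury in nuclei was at 2.07 thinned, 4.04 with injured barcodes and 3.98 with the unnamed cluster too, immediate early genes at 2.82 and 2.78 and proximal tubule transport at −1.06 and −1.29, with −0.38 in cells for both. A pseudocount of 10 gave 0.83 and 1.72 for tubular injury, 0.93 for immediate early genes in nuclei, 1.02 for chemokines in cells and 1.51 for class II in nuclei.

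Over all barcodes, rho was 0.513 weighted equally, 0.490 at 100 UMIs, 0.507 with TMM within preparations, 0.511 with mitochondrial genes left out, 0.478 at a pseudocount of 10 and 0.472 for barcodes that pass the filters. Weighted equally and thinned, mitochondrially encoded genes in nuclei were at −1.47, ribosomal proteins at 1.59 in cells and 0.87 and 0.83 in nuclei, proximal tubule transport at −0.56 and class II at 1.80 in cells. TMM within preparations gave −1.76 and −1.53 for mitochondrially encoded genes, 1.39 and 0.67 for ribosomal proteins, −0.53 and −1.44 for proximal tubule transport and 2.25 for class II in cells. Mitochondrial genes left out gave 1.04 and 0.76, −0.88 and −1.35, and in cells 1.90 for immediate early genes, 1.25 for tubular injury and 1.91 for class II. A pseudocount of 10 gave 1.18 and 2.18 for tubular injury, 2.26 and 1.85 for chemokines, and in nuclei 1.45 for immediate early genes and 2.20 for class II. Barcodes that pass the filters gave 0.13 for mitochondrially encoded genes in nuclei (sign changed, with mt-Atp6 at 0.10 and mt-Cytb at 0.074), −0.66 for red cell genes in nuclei (sign changed), 1.24 and 0.87 for ribosomal proteins, −0.63 and −1.26 for proximal tubule transport, and in cells 2.04 for immediate early genes, 1.46 for tubular injury and 1.997 for class II.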

Other observations

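No further hypothesis was tested in this part, and no tests were added to those above. Immune-like barcodes carried much more Cd74 in cells than in nuclei, at 24306, 18405 and 14692 CPM in control, 17 min and 27 min cells against 1868, 1753 and 2110 CPM in nuclei. In proximal tubule-like barcodes Cd74 stood at 47.1, 187 and 529 CPM in cells and at 14.2, 103 and 145 CPM in nuclei. Among immune-like cells, T cell-like barcodes took 22.9%, 19.6% and 29.2%, dendritic cell-like 11.4%, 19.7% and 15.9%, NK-like 4.16%, 5.58% and 9.51%, and B cell-like 7.23%, 5.28% and 5.88%. In immune-like nuclei, macrophage-like barcodes took 64.0%, 89.6% and 89.6%.

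Immune-like cells differed from immune-like nuclei in several lists, but also in makeup. Cells held a dendritic-like cluster of 506 and a T cell-like cluster of 156 barcodes with Top2a and Mki67 among their top genes. A macrophage-like cluster of 1417 cells had Ccl2 and Ccl7 among its top genes. Immune-like nuclei formed macrophage-like and T cell-like clusters alone. Differences within a cell type were not told apart from this makeup. Chemokine genes had 19 of 28 members up in cells and 4 down, with a median log2 of 2.65 (camera adjusted p = 0.000205, and adjusted p = 0.272 with an estimated correlation), and cell cycle genes 23 of 32 up (1.80, adjusted p = 6.93e-05, and adjusted p = 0.314 with an estimated correlation). Matrix genes had 17 of 25 up in nuclei and 3 down, with a median of −4.10 (adjusted p = 0.00102, and adjusted p = 0.572 with an estimated correlation). Their medians by state were 0 in control, −3.33 at 17 min and −3.32 at 27 min, and the macrophage-like nuclei cluster also counted 7 fibroblast markers. In endothelial-like barcodes, interferon response genes had 13 of 24 up in cells (1.20, adjusted p = 3.40e-05, and adjusted p = 0.320 with an estimated correlation). Haemoglobin genes took 0.0132% of UMIs in control proximal tubule-like cells, 0.00151% at 17 min and 0.000450% at 27 min, and 0.00347%, 0.000449% and 0.00233% in nuclei. By fry, which asks only whether a list's genes move one way, the smallest adjusted p in proximal tubule-like barcodes was 0.00146, shared by the immediate early, respiratory chain, nuclear-retained, NRF2 and p53 lists, and the lists above 0.05 were tubular injury (adjusted p = 0.182), interferon response (adjusted p = 0.210), matrix (adjusted p = 0.0982) and red cell genes (adjusted p = 0.395).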
